A study of Mus musculus with 16 samples.

How the data were processed

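Expression was measured in CD4+ T cells sorted by flow cytometry from lymph nodes of DO11 x rip-mOVA mice aged 6 weeks. These mice carry the DO11.10 T cell receptor, which recognises an ovalbumin peptide, and express membrane-bound ovalbumin from the rat insulin promoter. The labels give 4 groups by CD25, CD69 and tissue. Tcell_LN is CD25- CD69- (3 arrays), Tcell_panLN is CD25- CD69+ from pancreatic nodes (3 arrays), Treg_LN is CD25+ CD69- (6 arrays) and Treg_panLN is CD25+ CD69+ from pancreatic nodes (4 arrays). The series text names pancreatic and inguinal nodes, and the labels of both LN groups say lymph nodes without a site. CD69 state therefore differs in every comparison between an LN and a panLN group. Site differs with it as far as the LN cells came from other nodes, and the effects of site and CD69 state cannot be told apart. Each replicate was a pool of 14 mice. Whether replicates of different groups came from the same mice is not given in the sources used here. Tcell_LN and Tcell_panLN share no title number, so an effect of numbered pools or days, if any, could not be told from their difference.

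Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA by 2 cycles of amplification, and it was hybridised to Affymetrix mouse GeneChips. The deposited values are on the log2 scale, 1 value per probe set and array, for 22690 probe sets. Per the submitters' processing notes the tools were RMA and the affy package, with versions not given in the sources used here. RMA subtracts background, forces the arrays to a shared distribution and summarises the probes of a set. It compresses differences of dim probe sets and hides a change shared by most genes. Array medians of the deposited log2 values lay between 3.93 and 4.06. Arrays have no read depth, and the number of arrays limits the precision.

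The 64 control probe sets were left out of the tests. Of the others, 20380 were paired with 1 gene symbol by the platform annotation, 691 with several and 1555 were not listed. The Entrez identifiers of 20351 probe sets were found in the reference annotation GRCm38.p6, used for names only, and 0 symbols changed. For each of 12393 genes the probe set with the highest mean over all arrays was kept. More than 1 probe set was available for 4956 genes. List genes not paired with a tested probe set, Cd69, Tox2, Btla and Isg15 among them, are not analysed here.

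Differences were tested in R 4.3.3 with limma 3.58.1. A model of 4 group means was fitted to all 16 arrays, which left 12 residual and 5.1 prior degrees of freedom. The contrasts were both panLN against LN differences, both CD25+ against CD25- differences, and the interaction, the panLN minus LN difference in CD25- cells minus that in CD25+ cells. P-values are two-sided, from limma's empirical Bayes test, adjusted by Benjamini-Hochberg over the 12393 genes, and a gene was called below 0.05. The 24 gene lists (17 programmes and 7 sets of markers of other cells) held 374 genes, of which 314 were measured. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. Il2ra, the gene of the CD25 gate, belongs to the Treg core list, the effector Treg list and the list of genes low in Tfh cells. Its difference between CD25+ and CD25- cells follows from the sort. Other lists share members too, so their results are not independent. Ctla4 belongs to the Treg core, effector Treg and coinhibition lists. Pdcd1, Cd200, Tox and Izumo1r belong to the Tfh and coinhibition lists, and Il4 and Il21 to the Tfh and cytokine lists. Counts of members are given over all genes and adjusted over the list alone. Signal of the Gapdh and beta-actin control probe sets near the 3-prime end, minus that near the 5-prime end, served as a sign of RNA length and was compared by exact permutation tests. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

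Groups, tests, lists and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule takes the gate genes Cd4, Il2ra, Cd69 and Foxp3, the 10 largest rises and falls among called genes whose groups do not overlap, all Tfh list members, up to 4 members of every other list with the smallest adjusted p, and for the interaction the 5 largest differences each way. The text names part of that pool, and the part was picked with the values in view. Interaction values of Tfh list members were also named outside that rule's 10 genes, with their values in view. Alternatives were a filter on dim probe sets, other ways to handle several probe sets, quantile normalization, median centring, trended and robust variances, array weights, the title number as a block, fits of 2 groups, Treg_panLN 3 and 3C averaged to 1 sample, a stricter call at 1 log2 unit, fry, and leaving out each array. Leaving out both arrays numbered 1, or both numbered 6, and each array in turn for lists other than the Tfh list, was added after seeing the data.

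The procedure was tested on simulated data with the real gene means and spreads. In each comparison 100 genes were changed by 1 log2 unit and 100 by 2. For Tcell_panLN against Tcell_LN 93% and 99% were recovered, for Treg_panLN against Treg_LN 94% and 100%, for Treg_LN against Tcell_LN 92% and 100%, for Treg_panLN against Tcell_panLN 87% and 100%, and for the interaction 68% and 98%. False calls made up 4%, 4.9%, 4.95%, 6.5% and 4.6% of the calls. A list of 22 genes shifted by 0.5 log2 units was called by camera, and 2 of 100 unshifted lists fell below 0.05. Genes were simulated independently of each other, so this does not show the rate of false calls for correlated lists. In the measured data the estimated correlation was 0.334 for the cell cycle list and 0.836 for the interferon list.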

Results

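Gene expression was profiled on 16 arrays of CD4+ T cells that carried the DO11.10 T cell receptor, in mice whose pancreatic beta cells express the antigen of that receptor. By its title, the series asks about genes typical of follicular helper T cells in autoimmune diabetes. CD25, the receptor chain encoded by Il2ra, separated cells labelled Treg (regulatory T cells) from cells labelled Tcell, and CD69, an early activation marker, separated the pancreatic node groups from the others. The 4 groups were CD69- cells of lymph nodes, Tcell_LN (n = 3) and Treg_LN (n = 6), and CD69+ cells of pancreatic lymph nodes, Tcell_panLN (n = 3) and Treg_panLN (n = 4). CD69 state, and site as far as the LN cells came from other nodes, differed together between the panLN and the LN groups. Treg_panLN holds 2 arrays numbered 3, titled 3 and 3C, which were kept as separate samples, although the labels do not say whether their pools were separate. Values are log2 array signals with SD between arrays, and the labels give a pool of 14 mice per replicate. The median SD of a gene was 0.148 in Tcell_LN, 0.178 in Tcell_panLN, 0.177 in Treg_LN and 0.183 in Treg_panLN. Array medians lay between 3.93 and 4.06, and a fold is written with "about" where the mean of the lower group was under 3.93. Such folds, and log2 differences of the same genes, are not exact, and neither is their rank, since RMA compresses dim probe sets.

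Foxp3 and Il2ra followed the CD25 labels, and the CD69 gate was not checked on Cd69, which is not analysed here. Foxp3, the transcription factor that defines regulatory T cells, stood at 9.83 ± 0.34 (SD, n = 6) in Treg_LN and 9.38 ± 0.18 (SD, n = 4) in Treg_panLN, against 4.41 ± 0.25 (SD, n = 3) in Tcell_LN and 5.65 ± 0.28 (SD, n = 3) in Tcell_panLN. Il2ra stood at 8.39 ± 0.26 and 7.38 ± 0.28 in the 2 Treg groups and at 2.45 ± 0.24 and 3.29 ± 0.50 in the 2 Tcell groups, with the LN group first. Cd4 lay between 8.06 and 9.08 in the 4 group means. The first principal component held 42.0% of the variance and the second 18.1%, and the 4 groups occupied separate areas. Treg_LN 6A lay apart from the other 5 Treg_LN arrays, at -22.9 on the first component where the others ran from -8.2 to 8.7.

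**Figure D1:**
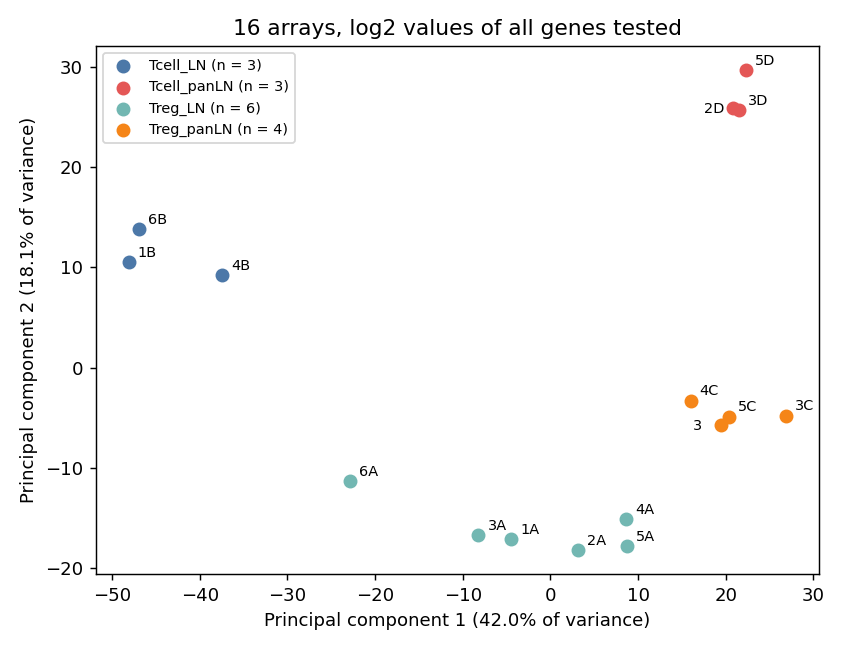
Principal components of the log2 values of the 12393 genes, with 1 point per array coloured by group and named by its title number and letter. Component 1 (42.0% of variance) runs from Tcell_LN on the left to the 2 panLN groups on the right, and component 2 (18.1%) separates Tcell_panLN at the top from both Treg groups.

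Among CD25- cells, the CD69+ cells of the pancreatic node carried much higher levels of follicular helper T cell (Tfh) genes than CD69- node cells. Cxcr5, the chemokine receptor that guides lymphocytes to B cell follicles, was about 55.6-fold higher, at 9.61 ± 0.06 in Tcell_panLN and 3.81 ± 0.35 in Tcell_LN (SD, n = 3 each). Pdcd1, which encodes the inhibitory receptor PD-1, was 30.0-fold higher, and Bcl6, the transcription factor that directs Tfh differentiation, was 7.83-fold higher. The cytokine genes Il4 and Il21, whose products act on B cells in the follicle, were about 14.5-fold and about 7.8-fold higher. The Tcell_LN means of Il4 and Il21 were 3.00 and 2.79. Icos rose 5.4-fold, Pou2af1 about 8.61-fold, Sostdc1 about 10.6-fold and Tnfsf8 5.69-fold. Of 22 measured members of the Tfh list, 17 rose and 1 fell over all genes, and 18 rose and 1 fell adjusted over the list alone. The list had a median difference of 2.11 log2 units (camera, adjusted p = 2.47e-16, and 5.42e-05 with an estimated correlation). The member that fell was Tox, by 0.94, and its other probe set gave 0.07 (adjusted p = 0.856). Maf, Il6ra, Cd40lg and Cxcr4 did not pass the test, with differences of 0.24, 0.05, -0.30 and 0.86.

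Naive and quiescence genes moved the other way. S1pr1, the receptor that lets lymphocytes leave lymph nodes, fell 7.36-fold, Klf2, which drives S1pr1, 4.82-fold, and Il7r, the receptor of a survival cytokine of resting T cells, 7.34-fold. Of 15 measured members of the naive and quiescence list 8 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 2.2e-05, and 0.0114 with an estimated correlation). The list of genes low in Tfh cells did not pass as a set, with 5 members lower and 3 higher (6 and 4 adjusted over the list alone, adjusted p = 0.114). Its higher members included Il2rb, about 4.2-fold, although the next probe set of Il2rb gave 0.23 (adjusted p = 0.557). The largest falls of single genes, as measured, included those of Myo6 (about 14.4-fold), Slc6a6 (9.84-fold), Sgk1 (9.65-fold) and Ppp3r1 (7.66-fold). Other probe sets of Slc6a6 and Ppp3r1 pointed the other way, at 0.15 for the next one of Slc6a6 and 1.71 for that of Ppp3r1 (adjusted p = 0.00478).

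Activation, inhibitory receptor and effector genes rose as well. Eomes and Gfi1, transcription factors of T cell differentiation, rose 15.1-fold and about 16.3-fold, the protease gene Gzmk about 16.5-fold, the prostaglandin receptor gene Ptger2 about 16.1-fold and Cd83 15.2-fold. In the T cell receptor activation list 14 of 22 rose and 1 fell (14 and 2 adjusted over the list alone), with Irf4 at 5.92-fold and Egr2 at 3.05-fold (adjusted p = 3.17e-07). In the coinhibition and anergy list 10 of 16 rose and 1 fell by both adjustments, that is over all genes and adjusted over the list alone, with Ctla4 at 7.42-fold and Lag3 at about 5.26-fold (adjusted p = 5.17e-07). In the cytokine and effector list 10 of 21 rose and 0 fell, and adjusted over the list alone also 10 and 0, with the chemokine gene Ccl5 at 9.8-fold and Ifng at about 3.37-fold (adjusted p = 0.000213). In the Th1 list 8 of 15 rose and 1 fell (9 and 1 adjusted over the list alone), with Tbx21 at about 4.24-fold up and Il18r1 at 5.09-fold down (adjusted p = 0.000137). The median of the cytokine list was 0.26, and 0.41 without Tcell_panLN 2D. With an estimated correlation these 4 lists had adjusted p of 0.0122, 0.00126, 0.0114 and 0.0286.

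Treg and cell cycle genes were also higher in Tcell_panLN. Of 22 Treg core genes 16 rose and 0 fell, also adjusted over the list alone (adjusted p = 4.42e-11, and 0.0032 with an estimated correlation). Tnfrsf4 rose 6.9-fold and Foxp3 2.36-fold. Il2ra rose about 1.8-fold, but without Tcell_panLN 2D its difference was 0.65 (adjusted p = 0.065), and its next probe set gave 0.44 (adjusted p = 0.215). The effector Treg list had 12 of 21 members higher and 1 lower, also adjusted over the list alone (adjusted p = 3.17e-07, but 0.0787 with an estimated correlation). Of 33 cell cycle genes 25 rose and 0 fell (27 and 0 adjusted over the list alone, adjusted p = 3.73e-10, but 0.125 with an estimated correlation). Mki67, a marker of dividing cells, rose 7.33-fold and Ccnb2 about 5.31-fold.

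Markers of other cells moved in part with the group. Of 14 B cell markers 4 were higher, also adjusted over the list alone, among them Cd79b about 2.75-fold and Ms4a1 2.7-fold, at 5.28 ± 0.63 and 5.41 ± 0.69 in Tcell_panLN (list adjusted p = 0.114). The list's median of 0.20 ran from 0.12 without Tcell_panLN 2D to 0.37 without 3D, neither called, and was called at 0.30 without Tcell_LN 6B (adjusted p = 0.0496). A further probe set of Ms4a1 gave 0.62 (adjusted p = 0.066). Cxcr5, Bcl6 and Pou2af1 are also expressed by B cells. The plasma cell genes Igha and Jchain were about 9.07-fold and about 3.64-fold higher with wide spread, and both calls were lost without Tcell_panLN 3D, at differences of 2.24 (adjusted p = 0.15) and 1.25 (adjusted p = 0.0507). The call of Igha was also lost without any 1 of Tcell_panLN 2D and the 3 Tcell_LN arrays, at 2.76, 3.28 (1B), 2.98 (4B) and 3.28 (6B). Klf6, Zfp36 and Btg2 of the dissociation stress list fell 5.2-fold, 4.35-fold and 4.72-fold, while the list did not pass (1 higher and 3 lower, also adjusted over the list alone, adjusted p = 0.228). For Klf6 the next probe set gave -0.21 (adjusted p = 0.392).

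In all, limma called 3323 of 12393 genes between Tcell_panLN and Tcell_LN, 1927 higher and 1396 lower, and 1236 of them differed by at least 1 log2 unit. With each array centred on its median the majority turned, with 1611 higher and 1659 lower. The 3-prime minus 5-prime signal of beta-actin, a sign of RNA length, was also higher in every Tcell_panLN array (1.31 to 1.59) than in every Tcell_LN array (0.63 to 0.83). The groups did not overlap for 38.4% of genes, where chance gives 10%. The median difference over all genes was 0.05.

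**Figure D2:**
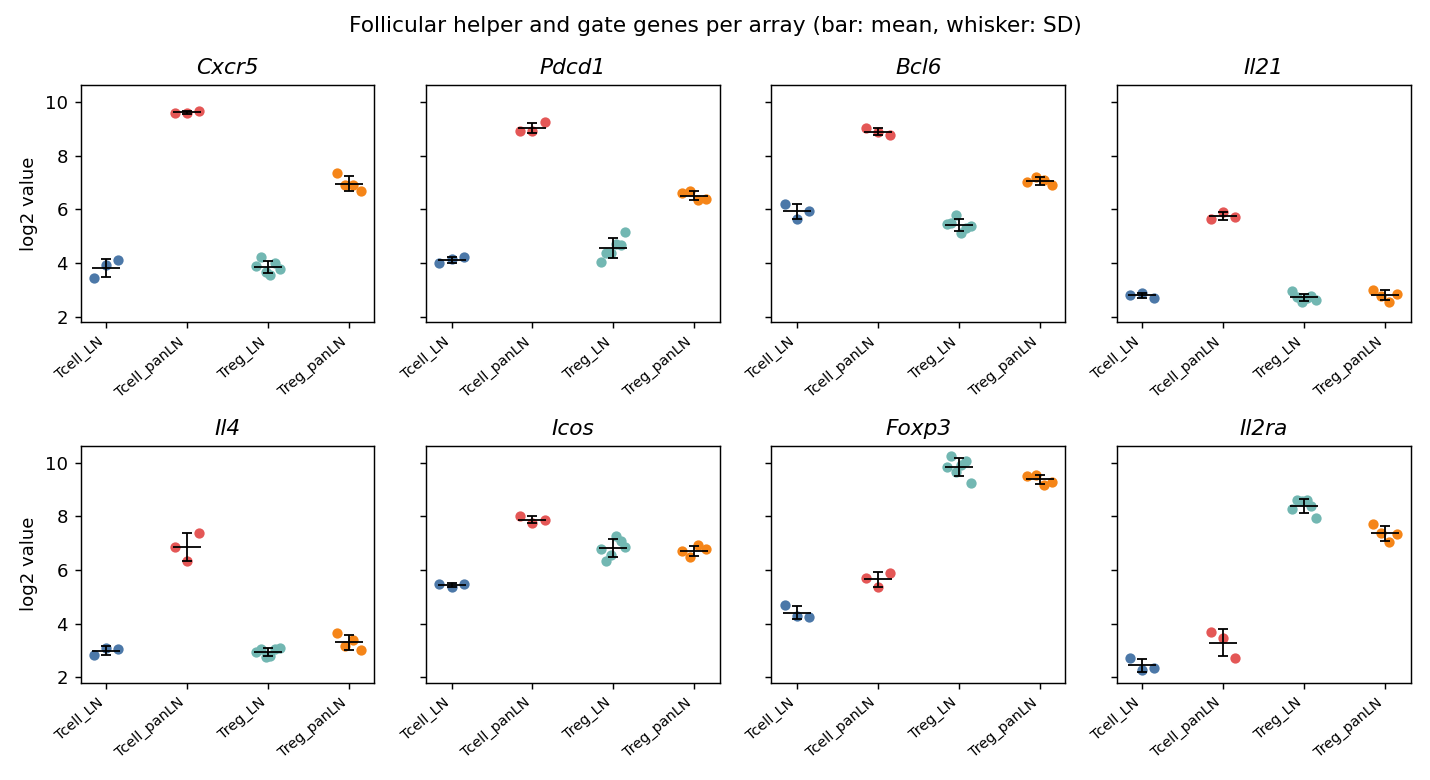
Log2 values of 8 genes in each array, with 1 point per array, a bar at the group mean and whiskers of 1 SD. Cxcr5, Pdcd1 and Bcl6 are highest in Tcell_panLN and intermediate in Treg_panLN, Il21 and Il4 are high in Tcell_panLN, and Foxp3 and Il2ra are high in both Treg groups.

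Among CD25+ cells, the CD69+ cells of the pancreatic node had higher levels of part of the Tfh genes. Cxcr5 was about 8.62-fold higher, at 6.96 ± 0.28 in Treg_panLN (SD, n = 4) and 3.85 ± 0.24 in Treg_LN (SD, n = 6), Pdcd1 3.87-fold and Bcl6 3.1-fold. Izumo1r, Batf, Pou2af1 and Cd200 rose 1.99-fold, 1.59-fold, about 1.71-fold and 1.47-fold. Il21 stood at 2.79 ± 0.19 and 2.72 ± 0.14 and did not pass the test (difference 0.08, adjusted p = 0.764), and neither did Il4 (0.36, adjusted p = 0.238) or Icos (-0.10, adjusted p = 0.791). In the Tfh list 7 of 22 rose and 1, Slamf6, fell (7 and 2 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00516, but 0.0542 with an estimated correlation. The median was 0.09 without Treg_panLN 3C and 0.52 after dim probe sets were filtered out, with the list called in both.

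Some of these calls rested on 1 array or 1 probe set. Cd200 and Pou2af1 were not called without Treg_panLN 5C (0.54 and 0.69), Cd200 not without 3C (0.45) and Pou2af1 not without Treg_panLN 3 (0.63). Slamf6 was not called without 3C (-0.58) or 5C (-0.52), and the next probe set of Bcl6 gave 0.05 (adjusted p = 0.896). For Slamf6 the next probe set gave -0.38 (adjusted p = 0.346).

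The largest rises, as measured, included, beside that of Cxcr5, those of Eomes (15.3-fold), Lyz1 (11.6-fold), Tgm2, a crosslinking enzyme (9.92-fold), Gfi1 (8.85-fold) and Lyz2 (about 7.12-fold). Lyz2 encodes the lysozyme of myeloid cells and Lyz1 that of Paneth cells of the gut. Lyz1 stood at 9.41 ± 0.57 in Treg_panLN, and its probe set without the suffix of cross-matching sets gave 0.26 (adjusted p = 0.124). In the myeloid and dendritic cell list 2 of 16 genes rose and 0 fell, also adjusted over the list alone, Lyz2 and Fcer1g, and the list did not pass (median 0.07, adjusted p = 0.395). The rise of Fcer1g, about 1.31-fold, lost its call without Treg_LN 3A (0.33), Treg_panLN 3 (0.31) or 3C (0.40). Ccr9, a homing receptor of gut and thymus, rose 3.82-fold.

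Among the genes that fell, the calcium-binding proteins S100a6 and S100a4 were about 12.7-fold and 8.53-fold lower, with S100a6 at 3.65 ± 0.52 in Treg_panLN and 7.32 ± 0.55 in Treg_LN, the galectin Lgals3 5.09-fold, Anxa2 4.37-fold and Vim, the intermediate filament vimentin, 3.82-fold. S1pr1, Klf2 and Prdm1, which encodes the repressor Blimp-1 that opposes Bcl6, fell 2.37-fold, 1.97-fold and 2.12-fold. In the list of genes low in Tfh cells 6 of 12 fell and 1 rose (6 and 3 adjusted over the list alone, adjusted p = 0.00944, but 0.114 with an estimated correlation). In the naive and quiescence list 3 of 15 fell and 0 rose (5 and 1 adjusted over the list alone, adjusted p = 0.00944, but 0.114 with an estimated correlation). The naive list's median of -0.17 was -0.11 without Treg_LN 1A or Treg_panLN 3C and -0.08 without Treg_LN 6A. Il2ra fell 2.02-fold, with its next probe set at -0.30 (adjusted p = 0.461), and Foxp3 did not pass (-0.45, adjusted p = 0.118).

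T cell receptor activation genes rose as a set. Of 22 members 13 rose and 0 fell (14 and 1 adjusted over the list alone, median 0.81, adjusted p = 1.52e-10, and 0.012 with an estimated correlation), with Tnfrsf9 at 6.38-fold, Cd83 at 4.78-fold and Egr2 at 2.71-fold. Irf4 rose 4.52-fold, and its next probe set gave 0.12 (adjusted p = 0.715). In the coinhibition and anergy list 9 of 16 rose and 0 fell (9 and 1 adjusted over the list alone, adjusted p = 0.000682, and 0.012 with an estimated correlation), with Lag3 at about 2.71-fold. In the Treg core list 12 of 22 rose and 3 fell (13 and 5 adjusted over the list alone, adjusted p = 0.00288, but 0.114 with an estimated correlation). The effector Treg list did not pass (8 of 21 higher and 5 lower, 9 and 5 adjusted over the list alone, adjusted p = 0.416).

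Cell cycle genes lay lower in Treg_panLN, with 5 of 33 called lower and 0 higher, also adjusted over the list alone (adjusted p = 0.00944, but 0.637 with an estimated correlation). The list's median of -0.25 was not called without Treg_LN 6A (-0.14, adjusted p = 0.0666) or Treg_panLN 5C (-0.08, adjusted p = 0.0619), and was -0.14 without Treg_LN 5A and -0.12 without Treg_panLN 4C. Mki67 fell 3.32-fold and Ccnb2 about 2.94-fold. Of 14 B cell markers 2 rose, also adjusted over the list alone (adjusted p = 0.0219, but 0.434 with an estimated correlation, and 0.0699 without Treg_panLN 5C), Ms4a1 2.18-fold and Cr2 about 1.51-fold. Ms4a1 was not called without Treg_panLN 5C (1.02, adjusted p = 0.0651). The interferon list had 1 of 16 members lower, Rtp4, also adjusted over the list alone (adjusted p = 0.0322, but 0.637 with an estimated correlation). This call rested on single arrays: its median of -0.25 was 0.04 without Treg_LN 1A (adjusted p = 0.376), and the call was also lost without Treg_panLN 3 (-0.23), 3C (-0.16) or 5C (-0.12). It was -0.43 without Treg_LN 3A and -0.49 without Treg_panLN 4C. Rtp4 differed by -0.89 and was not called without Treg_LN 1A (-0.77), 2A (-0.89) or 4A (-0.85), or without Treg_panLN 3 (-0.88), 3C (-0.96) or 5C (-0.73), and its next probe set gave -0.19 (adjusted p = 0.658).

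In all, 928 genes were called between Treg_panLN and Treg_LN, 553 higher and 375 lower, and 184 of them differed by at least 1 log2 unit. The groups did not overlap for 7.97% of genes, where chance gives 0.952%. With Treg_panLN 3 and 3C averaged to 1 sample 697 genes were called, and Cd200 (0.51), Fcer1g (0.36) and Rtp4 (-0.92) were not.

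Across the 12393 genes the panLN minus LN differences of CD25- and CD25+ cells correlated with Pearson r = 0.557 and Spearman rho = 0.498, although genes are not independent replicates. The jackknife standard error of r over arrays was 0.105. Of 635 genes called in both, 604 had the same sign. Cxcr5, Pdcd1, Bcl6, Eomes, Gfi1, Cd83 and Irf4 rose in both, and S1pr1, Klf2 and Myo6 fell in both, although further probe sets of Bcl6, Irf4 and Myo6 did not pass in CD25+ cells (0.05, 0.12 and -0.51). The 388 genes higher in both compare with 86 from independent lists, and the 216 lower in both with 42.2. These comparisons share no array. Over the genes called in CD25- cells, the CD25+ difference had a slope of 0.288 on the CD25- difference.

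**Figure D3:**
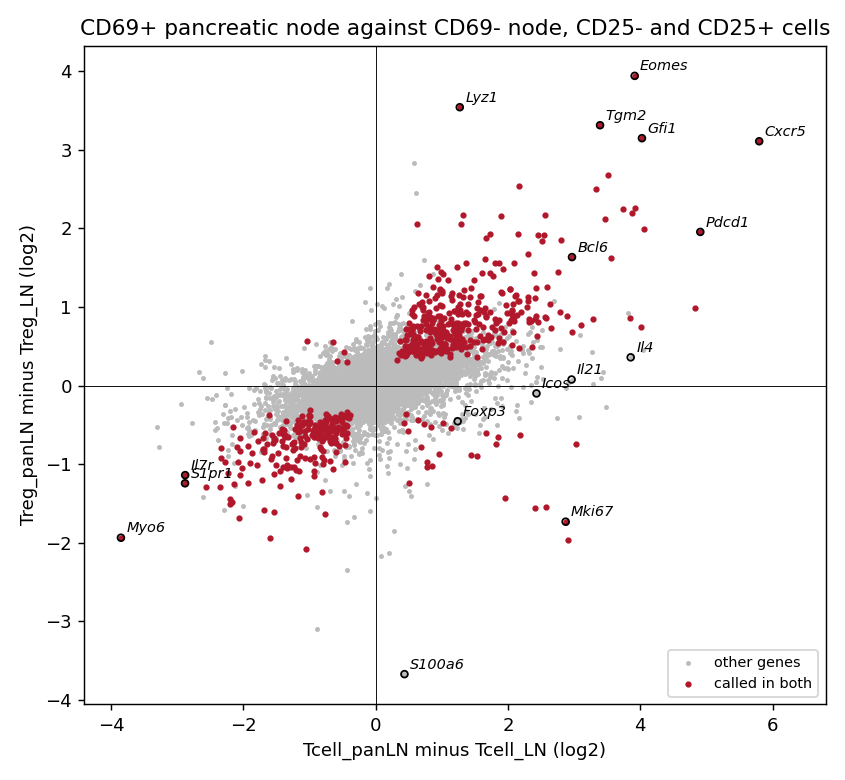
Each point is 1 of 12393 genes, with the Tcell_panLN minus Tcell_LN difference on the x axis and the Treg_panLN minus Treg_LN difference on the y axis, both in log2 units, and the 635 genes called in both in red. Cxcr5, Pdcd1 and Bcl6 lie at upper right, Il21, Il4 and Icos near 0 on the y axis, and Mki67 at lower right.

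The interaction asked whether the panLN minus LN difference was not the same in CD25- and CD25+ cells. Tfh genes rose more in CD25- cells. The excess was 3.50 ± 0.27 log2 units (SE) for Il4, 2.95 ± 0.27 for Pdcd1, 2.89 ± 0.17 for Il21, 2.69 ± 0.25 for Cxcr5 and 2.53 ± 0.24 for Icos. The excess of Bcl6 was 1.34, and that of its next probe set 0.44 (adjusted p = 0.256). Of 22 members 16 had a higher difference in CD25- cells and 1, Tox, a lower one (17 and 1 adjusted over the list alone, median 1.61, adjusted p = 1.99e-22, and 9.88e-06 with an estimated correlation). Cell cycle genes moved apart, with Mki67 at 4.60, Rrm2 at 4.87, Ccnb2 at 3.96 and 20 of 33 members higher and 0 lower (25 and 0 adjusted over the list alone, adjusted p = 2.41e-17, and 0.0364 with an estimated correlation). The excess of Tox, -0.75, was not called without any 1 of Tcell_LN 1B (-0.70) and 6B (-0.65), Tcell_panLN 2D (-0.68) and 3D (-0.75), Treg_LN 1A (-0.72), 2A (-0.72), 4A (-0.72) and 5A (-0.73), and Treg_panLN 3, 4C (-0.73 each) and 5C (-0.72). S100a6 differed by 4.11. The most negative values were those of Pdlim4 (-3.03), Siah1a (-2.85), Slc6a6 (-2.77), Nacc2 (-2.71) and Ppp3r1 (-2.70). The next probe set gave -0.78 for Siah1a (adjusted p = 0.0873), 0.14 for Slc6a6 and 0.97 for Ppp3r1, none of them called.

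Other lists with a larger rise in CD25- cells were Treg core (14 of 22 higher and 0 lower, also adjusted over the list alone, adjusted p = 4.37e-12), effector Treg (12 of 21 and 0, 13 and 0 adjusted over the list alone, adjusted p = 1.12e-11) and coinhibition and anergy (9 of 16 and 1, also adjusted over the list alone, adjusted p = 8.7e-08). So were cytokines and effector molecules (8 of 21 and 0, 9 and 0 adjusted over the list alone, adjusted p = 3.51e-06) and Th1 (6 of 15 and 1, 7 and 1 adjusted over the list alone, adjusted p = 0.000136). With an estimated correlation their adjusted p were 0.00235, 0.0257, 0.000702, 0.0027 and 0.0285. Several of these lists share members with each other and with the Tfh list, so they are not independent results. Naive and quiescence genes fell further in CD25- cells (7 of 15 lower and 0 higher, also adjusted over the list alone, adjusted p = 8.79e-05, and 0.0179 with an estimated correlation). The T cell receptor activation list had 3 of 22 members higher, also adjusted over the list alone (adjusted p = 0.0183, but 0.223 with an estimated correlation, 0.0662 without Tcell_LN 1B and 0.0713 without Treg_LN 6A). The stress list had 3 of 18 lower, also adjusted over the list alone (adjusted p = 0.0111, but 0.332 with an estimated correlation). Its median of -0.37 was not called without Tcell_LN 6B (-0.24) or Treg_panLN 3 (-0.22), and was -0.21 without Tcell_panLN 3D. The cytokine median of 0.40 was 0.23 without Tcell_panLN 3D, 0.72 without Tcell_panLN 5D and 0.26 without Treg_panLN 5C.

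In all the interaction was called for 1146 genes, 616 positive and 530 negative, or 531 and 600 with each array centred on its median, and 861 and 878 over all probe sets. The count was 674 without Tcell_LN 1B, 731 without Tcell_LN 6B and 1755 without Treg_LN 6A, and 556 without both arrays numbered 1.

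Among CD69- cells, CD25+ cells carried the regulatory T cell programme. Foxp3 was 42.7-fold and Il2ra about 61.7-fold higher in Treg_LN than in Tcell_LN, Socs2, a brake on cytokine signalling, about 41.3-fold, Ctla4, the inhibitory receptor, 14.0-fold, Klrg1 12.4-fold, Il2rb about 12.1-fold and Gpr83 11.6-fold. The Tcell_LN means of Il2ra and Socs2 were 2.45 and 2.94. Ikzf4, which encodes the transcription factor Eos, was 14.1-fold higher, while its next probe set gave 0.01 (adjusted p = 0.976). Of 22 Treg core genes 20 rose and 0 fell (21 and 0 adjusted over the list alone, median 2.77, adjusted p = 7.69e-40, and 1.66e-05 with an estimated correlation), and of 21 effector Treg genes 15 rose and 0 fell (16 and 0 adjusted over the list alone, adjusted p = 7.22e-20, and 0.00702 with an estimated correlation). Both lists hold Il2ra, whose rise follows from the sort for CD25. The coinhibition and anergy list had 7 of 16 higher and 1 lower, also adjusted over the list alone (adjusted p = 1.09e-05, and 0.00274 with an estimated correlation).

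The largest falls in Treg_LN, as measured, included those of Pdlim4 (about 24.6-fold), Nsg2 (about 14.1-fold), Rflnb (-3.46 log2 units), Adh1 (about 9.7-fold), Sema4f (9.01-fold) and Sgk1 (8.22-fold). The Tfh list did not stand apart from other genes (3 of 22 higher and 4 lower, also adjusted over the list alone, camera adjusted p = 0.902), although fry, which tests against no change, called it (adjusted p = 0.0374, median 0.01, mean 0.12). In this list Cxcr5, Pdcd1 and Il21 differed by 0.04, 0.43 and -0.08, none of them called. Its higher members included Izumo1r (3.9-fold) and Icos (2.6-fold). Bcl6 was 1.42-fold lower, a call that was lost without Tcell_LN 1B (-0.36) or 6B (-0.49) and with its next probe set (-0.04, adjusted p = 0.909). The naive and quiescence list lay lower (7 of 15 lower and 2 higher, 8 and 4 adjusted over the list alone, adjusted p = 0.0196, but 0.202 with an estimated correlation and 0.0687 without Treg_LN 6A, median -0.53, and -0.28 without Tcell_LN 6B), with Il7r 3.37-fold and Lef1 2.49-fold lower. T cell receptor activation genes were higher in 8 of 22 and lower in 1, also adjusted over the list alone (adjusted p = 0.00464, but 0.208 with an estimated correlation). Cell cycle genes were higher in 8 of 33 and lower in 0 (10 and 0 adjusted over the list alone, adjusted p = 0.00196, but 0.677 with an estimated correlation), with Mki67 at 4.25-fold. Lta and Gzmb rose 5.31-fold and about 3.3-fold and Fasl fell about 4.11-fold. Of the B cell markers 3 of 14 were higher, also adjusted over the list alone, with Cd79b at about 2.44-fold (list adjusted p = 0.352).

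In all 2179 genes were called between Treg_LN and Tcell_LN, 1255 higher and 924 lower, and 508 differed by at least 1 log2 unit. The groups did not overlap for 16.1% of genes, where chance gives 2.38%. The count was 1404 without Tcell_LN 1B, 1344 without Tcell_LN 6B and 1182 without both arrays numbered 1.

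Among CD69+ cells of the pancreatic node, CD25+ cells had the Treg programme and CD25- cells the higher Tfh and effector genes. Il2ra was about 16.9-fold and Foxp3 13.2-fold higher in Treg_panLN than in Tcell_panLN, Socs2 about 11.7-fold, Tgm2 7.32-fold, Gpr83 5.76-fold and Nrp1, a receptor of thymic Treg cells, 4.67-fold. Cxcr5, Pdcd1 and Bcl6 were 6.29-fold, 5.75-fold and 3.58-fold lower in Treg_panLN, Il4 about 11.7-fold and Il21 about 7.78-fold lower, and Sostdc1 differed by -3.32 log2 units. The next probe set of Bcl6 gave -0.49 (adjusted p = 0.135). Of 22 Tfh genes 16 were lower and 1, Izumo1r, was higher, also adjusted over the list alone (median -1.55, adjusted p = 1.2e-30, and 1.84e-06 with an estimated correlation). Maf, Tox, Il6ra, Cd40lg and Batf did not pass, and Cxcr4, 2.57-fold lower, was not called without any 1 of Tcell_panLN 2D, 3D and 5D and Treg_panLN 3 and 3C (-1.28, -1.38, -1.43, -1.38 and -1.10), or with Treg_panLN 3 and 3C averaged (-1.24).

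Effector genes were also lower in Treg_panLN. The protease gene Gzmk was about 14.8-fold, Cxcr3, the chemokine receptor of Th1 cells, 12.1-fold, Cxcl10 about 8.89-fold and Casp1 6.83-fold lower, and Ifng about 3.09-fold. In the cytokine and effector list 7 of 21 were lower and 0 higher (7 and 1 adjusted over the list alone, adjusted p = 1.28e-06), and in the Th1 list 5 of 15 and 0 (8 and 1 adjusted over the list alone, adjusted p = 5.2e-06). Of 33 cell cycle genes 17 were lower and 0 higher (24 and 0 adjusted over the list alone, adjusted p = 3.88e-20), with Mki67 5.73-fold lower. The cytokine median of -0.20 was -0.33 without Tcell_panLN 2D and -0.06 without Tcell_panLN 3D, and the Th1 median of -0.56 was -0.37 without Tcell_panLN 2D. With an estimated correlation these lists had adjusted p of 0.00231, 0.0135 and 0.0322. The list of genes low in Tfh cells had 4 of 12 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 7.24e-06, and 0.0117 with an estimated correlation), with Il2rb 4.62-fold and Klf2 2.62-fold higher and Id2 5.11-fold lower. Its higher members also included Il2ra, about 16.9-fold, which follows from the sort for CD25, and the list was not tested without Il2ra. The Treg core and effector Treg lists hold Il2ra as well. Treg core genes were higher in 19 of 22 and lower in 0 (20 and 0 adjusted over the list alone, adjusted p = 4.81e-39, and 9.27e-06 with an estimated correlation). Effector Treg genes were higher in 11 of 21 and lower in 3, also adjusted over the list alone (adjusted p = 1.78e-06, but 0.12 with an estimated correlation). Of the stress list 1 of 18 was called higher, also adjusted over the list alone (median 0.43, adjusted p = 0.0019, but 0.277 with an estimated correlation), and its median was 0.24 without Treg_panLN 3 and 0.69 without 3C. Cd4 was 1.71-fold lower, a call lost without Tcell_panLN 2D (-0.71), 3D (-0.74) or Treg_panLN 3C (-0.74) and with its next probe set (-0.80, adjusted p = 0.0834).

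In all 716 genes were called between Treg_panLN and Tcell_panLN, 332 higher and 384 lower, and 278 differed by at least 1 log2 unit. Here the majority turned with centring on the median, with 388 higher and 345 lower, and after dim probe sets were filtered out, with 312 and 284. The Gapdh 3-prime minus 5-prime signal was higher in every Treg_panLN array (2.40 to 2.58) than in every Tcell_panLN array (1.97 to 2.32). The groups did not overlap for 13.6% of genes, where chance gives 5.71%. The 2 comparisons of CD25+ with CD25- cells correlated with r = 0.241 and rho = 0.071 across genes, and 269 of the 328 genes called in both had the same sign.

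**Figure D4:**
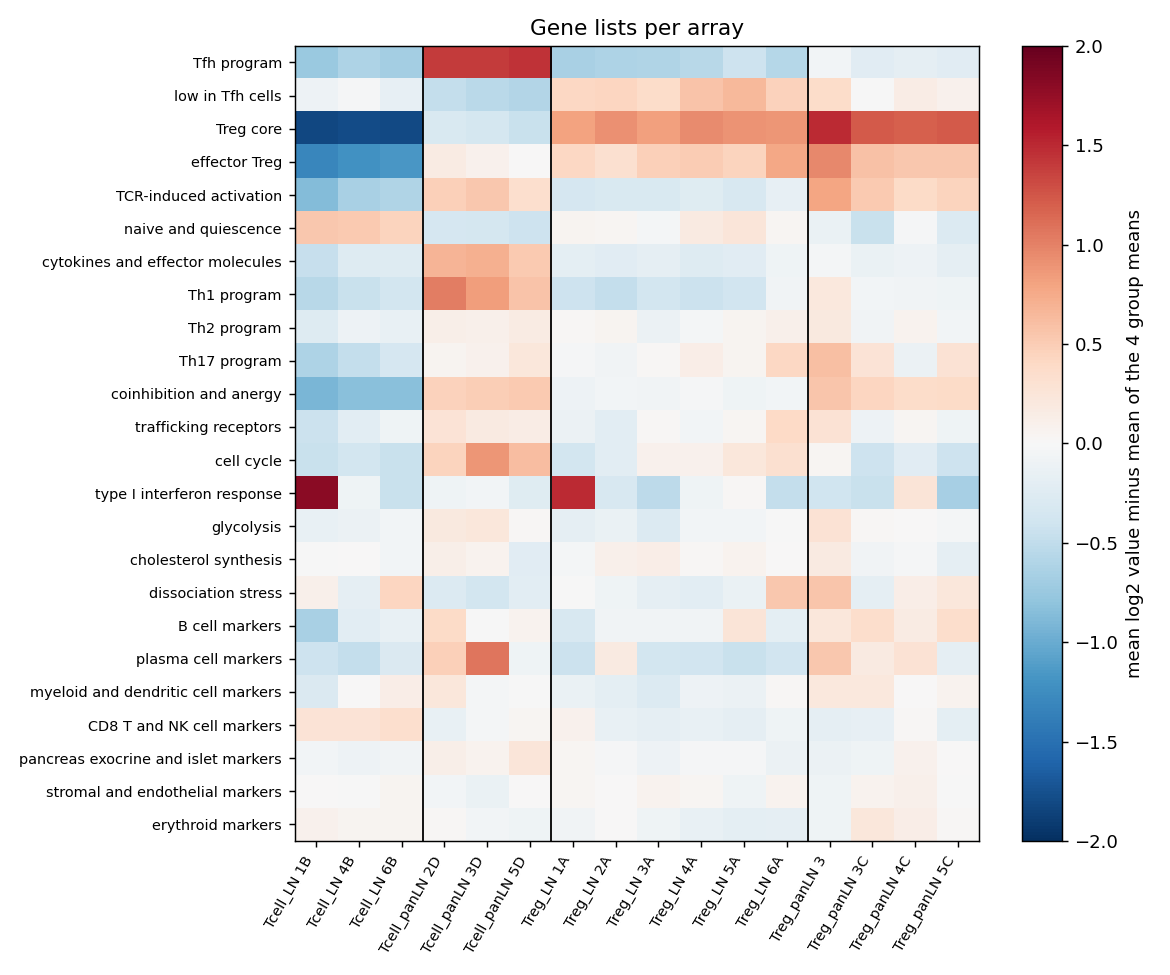
Mean log2 value of each of the 24 gene lists in each of the 16 arrays, minus the mean of the 4 group means, from blue (lower) to red (higher), with lines between groups. The Tfh list is highest in the 3 Tcell_panLN arrays, at 1.40 to 1.45, and the interferon list stands out in Tcell_LN 1B (1.80) and Treg_LN 1A (1.49).

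RNA length did not pass the adjusted test in any comparison, although 2 of 8 tests gave the smallest p that their design allows, with full separation of the arrays. The 3-prime minus 5-prime signal of Gapdh averaged 2.25 ± 0.22 in Tcell_LN, 2.20 ± 0.20 in Tcell_panLN, 2.24 ± 0.31 in Treg_LN and 2.48 ± 0.08 in Treg_panLN. That of beta-actin averaged 0.72 ± 0.10, 1.48 ± 0.15, 1.17 ± 0.39 and 1.60 ± 0.33 in the same order. In 8 two-sided exact permutation tests of the 4 comparisons the lowest adjusted p was 0.228, and 3 arrays against 3 cannot give an unadjusted p below 0.1. The unadjusted exact p were 0.7, 0.186, 0.976 and 0.0286 for Gapdh and 0.1, 0.114, 0.107 and 0.571 for beta-actin, in the order Tcell_panLN against Tcell_LN, Treg_panLN against Treg_LN, Treg_LN against Tcell_LN, and Treg_panLN against Tcell_panLN. The separated ones were beta-actin in the first and Gapdh in the last. Within Treg_LN both signals mostly rose along the first principal component (42.0% of variance). Treg_LN 6A, at -22.9 there, had 1.79 for Gapdh and 0.54 for beta-actin, and 4A, at 8.6, had 2.67 and 1.65. Tcell_LN lay lowest on that component and had the lowest beta-actin mean, while its Gapdh mean was near that of Tcell_panLN. The relation was not tested, so a part of RNA length in the group differences stays open.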

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

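The tests of mixed sorts, B cells, single arrays, lists without 1 array, shared numbers, array-wide shifts, RNA length and stress were chosen only after the results were seen, and the regroupings of the arrays were planned.

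Among the 7 of 22 Tfh list genes that rose in Treg_panLN, Tcell_panLN cells as the whole rise of Izumo1r are argued against, since its rise would need a share of at least 289% in every Treg_panLN array. A small share of Tcell_panLN cells in the sort stays open for the rest, since the implied shares cannot measure it. A share mixed in would be about the same for all transcripts, while the implied ones varied widely. For 39 abundant transcripts outside the list, picked for a higher level in Tcell_panLN than in Treg_LN, the median was 12.1% (quartiles 4.15 and 42.7, arrays 8.08 to 13.8). These can include genes that Treg cells raised themselves. The raised list genes implied 14.6% for Cxcr5, 13.6% for Pdcd1, 20.9% for Bcl6, 6.11% for Pou2af1, 30.4% for Cd200 and 62.4% for Batf, and are biased high, being picked for their rise. Il21, Il4, Sostdc1, Gpm6b and Tnfsf8, 5 of the list genes that were not raised, implied a median of 1.66% (0.733 to 9.31). They were picked for that and are biased low. Values of single arrays are argued against for 5 of the 7 genes, which were called without any 1 Treg_panLN array and higher in all 4 than in all 6 Treg_LN arrays (Cxcr5 at least 6.69 against at most 4.22), and stay open for 2, Cd200 and Pou2af1. B cells, which the sort for CD4 and the T cell receptor would remove, stay open, since their list had a median of 0.322 that passed at the preset correlation (adjusted p = 0.0219) and not with an estimated one (adjusted p = 0.434) or without Treg_panLN 5C (adjusted p = 0.0699), with Ighm, its brightest marker, at 0.34 (adjusted p = 0.185). A change of Treg cells at the site or with CD69 was not tested apart from these, and linear values from RMA are approximate.

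Interferon genes stood high in both arrays numbered 1, with the list 1.48 above its group mean in Treg_LN 1A and 1.37 in Tcell_LN 1B, where the next array reached 0.57. The list lay at percentile 100 among random lists of matched level in both arrays. It was picked because it stood out there, so this percentile cannot weigh a shift of the whole array. The deposited values held no such shift, with array medians of 3.94 in Tcell_LN 1B and 3.96 in Treg_LN 1A, although RMA would remove one. Myeloid or dendritic cells, which the sort for CD4 and the T cell receptor would remove, stay open, since their list deviated by -0.24 in 1B and -0.00 in 1A (mean -0.120), where the SD of its deviations in the other arrays was 0.11, and Cst3, its brightest marker, by -0.32 and 0.06 (SD 0.20). A pool of mice or a day shared by arrays of 1 number may be the source and stays open, since numbers held 83.7% of the variance with a permutation p of 0.06 (adjusted p = 0.435 over 24 lists). No biological explanation was tested, and the labels give no infection or treatment.

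Treg_LN 6A held 7 of the 21 far values given below, as did Treg_panLN 3, which was not weighed here. A share of Tcell_LN cells may contribute, since transcripts specific to Tcell_LN implied 4.6% in 6A and -1.49% to 1.01% in the others. It cannot be the source of all far values. Tcell_LN cells would lower the effector Treg list and Itgae, which were higher in Treg_LN than in Tcell_LN. In 6A that list stood 0.29 above its group mean (others -0.17 to 0.02) and Itgae was at 8.04 (others 7.25 to 7.49). Nor could a share this small lower Iqgap2 and Itih5 as far as given below. RNA length may contribute too, since 6A lay outside the other arrays on 2 of 2 controls, with the lowest 3-prime minus 5-prime signal (1.79 for Gapdh and 0.54 for beta-actin). Stress before lysis stays open without a test, since the dissociation stress list of 6A, at percentile 100 among matched random lists, is itself 1 of the 7 values. These explanations do not exclude each other, and no biological explanation was tested.

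Of 245 values tested in the groups of 4 and 6 arrays, 21 had 1 array far from the others, where chance marks about 1 in 20 groups. In Treg_LN 6A these were Dusp6 at 4.99 (others 2.98 to 3.52), Iqgap2 at 6.21 (7.05 to 7.44), Itgae at 8.04 (7.25 to 7.49), Itih5 at 8.65 (9.66 to 10.17), Tox at 4.06 (3.43 to 3.56), the Th1 list at -0.06 (-0.47 to -0.37) and the stress list at 0.54 (-0.21 to -0.01). Treg_LN 1A had Eomes at 5.50 (4.35 to 4.71) and the interferon list at 1.49 (-0.53 to 0.03). Fcrl1 was at 4.34 in Treg_LN 5A (3.32 to 3.69) and the plasma cell list at 0.17 in Treg_LN 2A (-0.44 to -0.36). In Treg_panLN 3 Gata3 was at 8.77 (7.98 to 8.02), Gzmk at 4.01 (3.55 to 3.56), Nfatc1 at 7.65 (6.89 to 6.95), the Treg core list at 1.49 (1.20 to 1.23), the effector Treg list at 0.97 (0.53 to 0.58), the Th1 list at 0.21 (-0.09 to -0.05) and the glycolysis list at 0.29 (-0.03 to 0.02). Treg_panLN 4C had Cd40lg at 3.06 (3.37 to 3.40) and Siah1a at 7.90 (5.87 to 6.11), and Treg_panLN 3C had Tox at 3.19 (3.43 to 3.45). Without Treg_panLN 3, 766 genes were called between Treg_panLN and Treg_LN in place of 928.

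The panLN minus LN difference was not the same in CD25- and CD25+ cells for 1146 genes by the interaction test. List medians of that difference of differences were 1.613 (Tfh), 1.346 (Treg core), 0.978 (effector Treg), 0.265 (T cell receptor activation), -0.735 (naive and quiescence), 0.398 (cytokines), 1.047 (Th1), 0.968 (coinhibition), 1.035 (cell cycle) and -0.37 (stress). Without 1 array the median of the cytokine list ran from 0.229 (Tcell_panLN 3D) to 0.722 (Tcell_panLN 5D), with 0.261 without Treg_panLN 5C. The stress list was at -0.205 without Tcell_panLN 3D, and was not called without Tcell_LN 6B (-0.235) or Treg_panLN 3 (-0.220). The activation list was not called without Tcell_LN 1B or Treg_LN 6A (0.233 and 0.296). The genes with the largest values were Rrm2 (4.87), Mki67 (4.60), Pclaf (4.12), S100a6 (4.11) and Ccnb2 (3.96), and on the negative side Pdlim4 (-3.03), Siah1a (-2.85), Slc6a6 (-2.77), Nacc2 (-2.71) and Ppp3r1 (-2.70). The next probe set of Pclaf gave 0.02. Tfh list members were Il4 (3.50), Sostdc1 (3.31), Pdcd1 (2.95), Il21 (2.89), Cxcr5 (2.69), Icos (2.53), Pou2af1 (2.33), Gpm6b (2.32), Slamf6 (2.28), Tnfsf8 (2.02), Ascl2 (1.68), Sh2d1a (1.52), Cebpa (1.52), Cd200 (1.37), Bcl6 (1.34), Izumo1r (1.30) and Tox (-0.75). For Sostdc1 the next probe set gave 0.77 (adjusted p = 0.089).

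Of 2246 probe sets not paired with 1 gene, 466 were called between Tcell_panLN and Tcell_LN, 81 between Treg_panLN and Treg_LN, 277 between Treg_LN and Tcell_LN and 61 between Treg_panLN and Tcell_panLN.

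Other splits of the arrays tested whether chance could give results as large, the real split counted. Chance is made unlikely, but not excluded, for the 928 genes of Treg_panLN against Treg_LN (1 of 100 splits, highest other 17). The same holds for the 2179 of Treg_LN against Tcell_LN (1 of 84, highest other 1078). It also holds for the 716 of Treg_panLN against Tcell_panLN (1 of 35, highest other 171). Shares of 1 in 84 and 1 in 35 are the smallest that these designs can give. The splits also treat arrays as independent, while arrays of 1 number may share a pool or day. Chance stays open for the Tfh list median of 0.169 in Treg_panLN against Treg_LN (5 of 100, highest other 0.205). For the interaction the splits shuffled the CD25 labels within each CD69 level. They tested for no CD25 difference at all, and so cannot say whether chance gives an interaction as large. The real split gave 1146 genes (1 of 100, highest other 223) and a Tfh list median of 1.613 (2 of 100, highest other 1.801). The 10 splits of Tcell_panLN and Tcell_LN are too few for a share under 0.05, with 3323 genes in the real split and 0 as the highest other, and list medians of 2.108 and 0.800.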

How the results depend on the processing

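Leaving out both arrays numbered 1, or both numbered 6, and each array in turn for lists other than the Tfh list, was chosen after seeing the data, and all other alternatives were planned. Counts of called genes moved by over 1.5 times in the following cases. A further limit of 1 log2 unit, stricter by construction, left 1236 genes for Tcell_panLN against Tcell_LN, 184 for Treg_panLN against Treg_LN, 508 for Treg_LN against Tcell_LN, 278 for Treg_panLN against Tcell_panLN and 624 for the interaction. All probe sets, a larger number of features, gave 5602, 3549 and 1739 for the first, the third and the interaction. Without both arrays numbered 1, and so with fewer arrays, Treg_LN against Tcell_LN gave 1182 and the interaction 556. Without 1 array at a time the counts ran from 2698 to 3536, 650 to 991, 1344 (Tcell_LN 6B) to 2756 (Treg_LN 6A), 562 to 800 and 674 (Tcell_LN 1B) to 1755 (Treg_LN 6A), in the same order. With Treg_panLN 3 and 3C averaged they were 3402, 697, 2229, 615 and 1057. Quantile normalization and median centring moved the share of higher calls by under 10 points, at most from 59.6% to 50.1%, for Treg_panLN against Treg_LN. Median centring still turned the majority of calls in 3 comparisons, from 58.0% to 49.3% higher for Tcell_panLN against Tcell_LN, 46.4% to 52.9% for Treg_panLN against Tcell_panLN and 53.8% to 46.9% for the interaction, and so did the filter on dim probe sets for Treg_panLN against Tcell_panLN (312 higher and 284 lower) and all probe sets for the interaction (861 and 878).

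With the title number as a block, 1727 genes were called between Tcell_panLN and Tcell_LN and 553 in the interaction, and of these 1670 and 510 were called without the block. Tcell_LN and Tcell_panLN share no number, so under the block their difference could be estimated only through the Treg arrays. Whether the numbers pair the samples stays open. Of 14 pairs sharing a number across groups 5 correlated above 0.1 (-0.172 to 0.388), and 5 of 16 arrays correlated best with their own number. The median correlation was 0.0385 for pairs sharing a number and -0.021 for the others, and limma's consensus correlation over genes was 0.002. The pairs of Treg_LN and Tcell_LN gave 0.182 (number 1), 0.108 (number 4) and 0.388 (number 6). Under the block 1465 genes were called between these 2 groups, against 2179 without it. Under the block the interferon list of Treg_panLN against Treg_LN had a median of 0.036 (adjusted p = 0.346) and Il6ra, not called otherwise, differed by -0.943 between Tcell_panLN and Tcell_LN (adjusted p = 0.0474). The stress list of Treg_panLN against Treg_LN and the Th17 list of Treg_LN against Tcell_LN passed camera there and not without the block, with medians of 0.387 and 0.361 (adjusted p = 0.00889 and 0.0362), while fry called the Th17 list without the block (adjusted p = 0.0157). The cause was not tested.

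The Tfh list kept its direction and call in Tcell_panLN against Tcell_LN and in the interaction under every alternative run, with medians of 2.101 to 2.197 and 1.591 to 1.716 without 1 array. In Treg_panLN against Treg_LN the median of 0.169 kept its call (0.09 to 0.253 without 1 array, highest adjusted p 0.0146) but not with an estimated correlation (adjusted p = 0.0542). Of 39 other list results that were called, 33 were called without any 1 array and 6 were not, and of 78 not called 7 were called without at least 1 array. The interferon list of Treg_panLN against Treg_LN turned from -0.254 to 0.035 without Treg_LN 1A (-0.485 to 0.035 over all arrays left out). The correlation of the panLN minus LN differences ran from 0.479 to 0.596 without 1 array. With beta-actin in place of Gapdh the RNA length difference was 0.766 between Tcell_panLN and Tcell_LN and 0.458 between Treg_LN and Tcell_LN, against -0.052 and -0.006.

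The next probe set turned the sign of Slc6a6 (0.155), Ppp3r1 (1.713), Tox (0.067), Cmpk2 (0.085) and Prf1 (0.003) in Tcell_panLN against Tcell_LN, of Acot6 (-0.037) in Treg_panLN against Treg_LN, and of Slc6a6 (0.140), Ppp3r1 (0.969) and Tox (0.326) in the interaction. The cause was not tested. Of 6755 alternative values of the 232 called gene results, 6632 kept direction and call, 114 lost the call and 9 reversed. Many of these values came from leaving out 1 array. The next probe set, which only part of the genes have, gave 28 of the lost calls and all 9 reversals. Of 976 alternative values of uncalled results 17 became called in the same direction and 1 in the opposite one. Dim probe sets, where RMA compresses differences, limit what can be seen.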

Other observations

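Tests of lists without 1 array were chosen after seeing the data, all other tests of lists in this part were planned, and the genes named were picked from the pool of the naming rule with their values in view.

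Trafficking receptors moved both ways. Between Tcell_panLN and Tcell_LN 5 of 19 rose and 4 fell (5 and 5 adjusted over the list alone, adjusted p = 0.957), with Itgae, the integrin chain CD103, 4.85-fold higher and Itgb7 and Selplg, the ligand of P-selectin, lower (2.75-fold and 2.89-fold). The list's median there was -0.06 and its mean 0.44. Between Treg_panLN and Treg_LN 3 rose and 5 fell (6 and 5, adjusted p = 0.272, median -0.15 and mean 0.02), with Ccr2, a receptor of inflammatory chemokines, about 2.58-fold lower. In Treg_LN against Tcell_LN 4 rose and 3 fell (4 and 4, adjusted p = 0.694), with Itgae 8.0-fold and Ccr6 4.04-fold higher, and in Treg_panLN against Tcell_panLN 4 rose and 3 fell (6 and 4, adjusted p = 0.567, median 0.17 and mean -0.17). Its interaction had 5 members each way (6 and 6, adjusted p = 0.536).

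Th2 and Th17 lists did not pass by camera in any comparison of all arrays without the block. With the title number as a block the Th17 list of Treg_LN against Tcell_LN passed, as given above. Between Tcell_panLN and Tcell_LN Il4 rose and Il4ra, the receptor of its product, fell 2.31-fold, the 2 called of 11 Th2 genes, also adjusted over the list alone (adjusted p = 0.866). Gata3, the transcription factor of Th2 cells, was 2.65-fold higher in Treg_LN than in Tcell_LN (1 of 11, also adjusted over the list alone, adjusted p = 0.552) and 2.49-fold higher in Treg_panLN than in Tcell_panLN (2 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.567, median 0.02 and mean -0.09). Of 9 Th17 genes 3 rose in Tcell_panLN, also adjusted over the list alone (adjusted p = 0.21, median -0.01 and mean 0.61), among them Ccr6 3.49-fold, and 3 in Treg_LN against Tcell_LN, also adjusted over the list alone (adjusted p = 0.0756). The median of 0.23 in the latter was 0.12 without Treg_LN 6A (adjusted p = 0.258), and it was called without Tcell_LN 6B (0.32), Treg_LN 1A (0.20) or 2A (0.29), or Treg_panLN 3 or 4C (0.23 each). In Treg_panLN against Treg_LN 0 Th2 genes and 1 Th17 gene, Batf, were called (adjusted p = 0.9 and 0.395). In Treg_panLN against Tcell_panLN 1 Th17 gene, Rora, was higher (2 adjusted over the list alone, adjusted p = 0.567). In the interaction the Th2 list had a median of -0.03 and a mean of 0.27 (adjusted p = 0.739) and the Th17 list adjusted p = 0.225.

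Metabolic lists did not pass by camera either. Hk2, the first enzyme of glycolysis, was about 2.24-fold higher in Tcell_panLN than in Tcell_LN and 2.12-fold higher in Treg_panLN than in Treg_LN, where 3 of 14 glycolysis genes rose and 1 and 2 fell (3 and 1, and 6 and 2, adjusted over the list alone, adjusted p = 0.289 and 0.179). Slc2a3, a glucose transporter, was 2.34-fold higher in Treg_LN than in Tcell_LN (3 higher and 3 lower, 3 and 5 adjusted over the list alone, adjusted p = 0.736) and 1.75-fold higher in Treg_panLN than in Tcell_panLN (1 higher, 2 and 1 adjusted over the list alone, adjusted p = 0.501). For the 14 cholesterol synthesis genes adjusted p were 0.786, 0.272, 0.9 and 0.602 in the 4 comparisons, with Sc5d 2.97-fold higher in Treg_panLN than in Tcell_panLN. The interaction of both lists had adjusted p = 0.739.

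The interferon list had 1 of 16 higher and 3 lower between Tcell_panLN and Tcell_LN (1 and 4 adjusted over the list alone, adjusted p = 0.107), and its median of -0.84 was -0.17 without Tcell_LN 1B (adjusted p = 0.875), while it was called without Tcell_LN 4B (-0.97) or 6B (-1.23). Ifit2 and Cmpk2 fell 2.81-fold and 4.42-fold, and without Tcell_LN 1B they differed by -0.92 (adjusted p = 0.0882) and -1.17 (adjusted p = 0.146). The call of Ifit2 was also lost without Tcell_panLN 5D (-1.34) and that of Cmpk2 without Tcell_panLN 2D (-2.15) or 3D (-2.06), and the next probe set of Cmpk2 gave 0.09. The list had adjusted p = 0.342 in Treg_LN against Tcell_LN (median -0.46), 0.567 in Treg_panLN against Tcell_panLN and 0.659 in the interaction (median -0.40). Without Tcell_LN 1B the first and the last of these medians turned sign, to 0.18 and 0.41, neither called, while that of Treg_LN against Tcell_LN was called without Tcell_LN 6B (-0.73) or Treg_LN 1A (-0.65).

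Lists left over from the comparisons above had these results. Genes low in Tfh cells had adjusted p = 0.369 in Treg_LN against Tcell_LN (4 of 12 higher and 4 lower, 6 and 4 adjusted over the list alone) and 0.536 in the interaction, where the median was 0.07 and the mean -0.11. Cytokines had adjusted p = 0.558 in Treg_panLN against Treg_LN, with Gzmb about 2.7-fold lower, and 0.9 in Treg_LN against Tcell_LN, where the median was -0.05 and the mean 0.13. The Th1 list had adjusted p = 0.233 in Treg_panLN against Treg_LN, with Tbx21 about 2.05-fold higher, and 0.694 in Treg_LN against Tcell_LN. In Treg_panLN against Tcell_panLN T cell receptor activation had adjusted p = 0.501, naive and quiescence 0.0512 (median 0.20, with a range of 0.11 without Treg_panLN 3 to 0.27 without Treg_panLN 4C, neither called, called at the same median without Tcell_LN 4B or 6B or Treg_LN 2A, 4A or 6A, and at 0.26 without Treg_panLN 3C) and coinhibition 0.764. The stress list had adjusted p = 0.272 in Treg_panLN against Treg_LN (median 0.24, but 0.06 without Treg_panLN 3, 0.12 without Treg_LN 2A and 0.14 without 5A, and called without Treg_LN 6A at 0.28 and without Treg_panLN 3C at 0.39), with Hspe1 1.6-fold higher, and 0.694 in Treg_LN against Tcell_LN.

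Markers of other cells gave few calls. Klrd1, a receptor of NK and CD8 T cells, was about 2.98-fold lower in Tcell_panLN and about 5.18-fold lower in Treg_LN than in Tcell_LN (3 and 2 of 9 CD8 T and NK cell markers lower and 0 higher, 3 and 0, and 2 and 1, adjusted over the list alone, adjusted p = 0.114 and 0.105, the latter with a median of -0.05 that was -0.14 and called without Tcell_LN 1B and -0.03 without 6B). That list had adjusted p = 0.495 in Treg_panLN against Treg_LN, 0.501 in Treg_panLN against Tcell_panLN and 0.134 in the interaction. Cela1, an elastase of the exocrine pancreas, was 4.36-fold higher in Tcell_panLN than in Tcell_LN, the 1 called of 16 pancreas markers, also adjusted over the list alone (adjusted p = 0.393), while Treg_panLN against Treg_LN had 0 (adjusted p = 0.855). Pecam1, of endothelium and naive T cells, fell 2.01-fold in Tcell_panLN, the 1 called of 12 stromal markers (adjusted p = 0.393), and Car2 rose about 1.39-fold in Treg_panLN against Treg_LN, the 1 called of 4 erythroid markers (2 adjusted over the list alone, adjusted p = 0.293). The plasma cell list had adjusted p = 0.393 between Tcell_panLN and Tcell_LN and 0.293 between Treg_panLN and Treg_LN, the myeloid list 0.797 in the first, and the B cell list 0.501 in Treg_panLN against Tcell_panLN and 0.739 in the interaction. Median and mean had opposite signs for the stromal list in Treg_LN against Tcell_LN (-0.01 and 0.004), in Treg_panLN against Tcell_panLN (-0.001 and 0.08) and in the interaction (0.002 and -0.08), and for the myeloid list in Treg_panLN against Tcell_panLN (-0.06 and 0.06), with adjusted p of 0.9, 0.602, 0.583 and 0.764.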
